A study of Mus musculus with 3 samples.

How the data were processed

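Single-cell RNA sequencing was carried out on cells of mouse embryos at embryonic day 3.5, the blastocyst stage, in 3 libraries of 96 cell barcodes each, which are called replicates 1 to 3. Per the labels' protocols, embryos of a mouse line that carries an H2B-mCherry reporter at Klf2 were collected at embryonic day 2.5, cultured under static and shaking conditions, freed of the zona pellucida, dissociated in medium without calcium and magnesium and picked as single cells by mouth pipette from mCherry-positive embryos. The labels do not say which cells came from static or from shaking culture and give no mCherry value per cell, so the libraries form 1 group and no contrast between culture conditions was made. Per the labels, cDNA was made with an optimized Smart-seq2 protocol in which an oligo(dT) primer carried an 8 nt cell barcode and an 8 nt unique molecular identifier, a random tag that marks each captured molecule. After 17 and 5 cycles of PCR the 3' ends were captured and sequenced as 150 bp pairs, with a stated average of 200 M reads per library.

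The deposited values were whole-number counts per gene and cell barcode, not normalized, for 23154 gene symbols in each library. The submitters' processing notes name CASAVA 1.8, HISAT2, HTSeq and the mouse build mm10; versions of HISAT2 and HTSeq, the gene annotation, the strand setting and the use of the molecular identifiers are not given in the sources used here. Whether the deposited counts are molecules or reads was not settled from the values. Among genes seen in few cells, 47.2%, 44.1% and 37.6% of the values above 0 equalled 1 in replicates 1, 2 and 3, with 90th percentiles of 11, 21 and 30, and no value exceeded the 65536 tags that 8 nt allow. Counts are therefore called counts throughout, and intervals and floors cover counting error only.

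A barcode was kept as a cell when at least 2000 genes had a count, which retained 83, 64 and 78 barcodes of replicates 1 to 3 and left out 13, 32 and 18. No doublet caller was run, because cells were picked by hand; an alternative left out cells whose total was over 2.5 times the median of their class in their library. Cells were clustered on 54 marker genes alone, namely 18 of trophectoderm (TE), 6 of inner cell mass (ICM), 10 of epiblast (EPI) and 20 of primitive endoderm (PrE). Markers without variation between cells, Sox2 among them, dropped out of the clustering. Values were log2 CPM plus a pseudocount of 1 scaled to the median cell, centred per gene within a library and scaled, followed by 10 principal components, 15 neighbours and Leiden clustering at resolution 0.5. A cluster took the name of its highest marker score if that exceeded the other cells by 0.25 on the log2 scale. Its 10 leading genes also had to hold at least as many markers of that class as of the other, so a tie passed. The ICM score averaged ICM and EPI markers, without PrE markers. At least 3 markers of the class had to be detected, and shallow clusters without a leading marker stayed unnamed. This definition was set after the data had been seen. ICM-like cells were then clustered again on the EPI and PrE markers.

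The cells of a class were summed within each library, for classes with at least 8 cells, so that the library was the replicate and cells were not. Genes were retained by filterByExpr, scaled by TMM factors and tested with edgeR's quasi-likelihood test with the library as a block, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Both classes of a pair came out of the same libraries, which is where the pairing comes from. Marker genes used for clustering were left out of the counts of genes and of the lists. Classes were drawn on the same cells that were then tested, so the p-values do not include the uncertainty of drawing them. Nothing in the labels says that the 3 libraries came from separate cultures or animals, and p-values measure only the spread between these samples, which may be technical.

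For comparison between TE-like and ICM-like cells, 22 gene lists with 415 genes were fixed. They covered the flow response and KLF2 pathway, mechanosensitive channels and polycystins, the KLF family, YAP and TEAD targets, Hippo components, fluid transport and tight junctions, actomyosin and adhesion, FGF and ERK signalling, naive pluripotency regulators, BMP, Nodal and TGF beta signalling, Wnt signalling, Notch signalling, glycolysis, oxidative phosphorylation, cholesterol synthesis, lysosome and endocytosis, S phase, G2 and M phase, p53 and apoptosis, dissociation and immediate early genes, ER stress and the unfolded protein response, and DNA methylation and chromatin. Lists were tested with limma's camera at its preset correlation, again with an estimated correlation, and with fry, which asks whether the genes of a list move one way and does not compare them with other genes. With an estimated correlation camera uses the residual degrees of freedom, which are few with 3 libraries. A pass over all lists was then hard to reach whatever the genes did, so a loss there cannot show an unchanged list. Another 5 lists held markers of cumulus or granulosa cells, oviduct epithelium, blood, oocytes or polar bodies, and fibroblasts. The genes named in the text were Klf2, the 10 called genes with the highest and the 10 with the lowest log2 fold change at a mean log2 CPM of at least 5 and the same sign in every library, and up to 3 called members of each list with the lowest adjusted p. Clustering markers, predicted-gene and Rik-type names were left out of this rule. The markers, lists, tests, named-gene rule and most of the alternatives below were fixed before the data were examined. Genes named outside the rule, where a count was small, were chosen after their values were seen. A result for 1 gene that the rule selects is not reported here.

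Genes that vary with Klf2 were sought by a partial Spearman correlation, adjusted for the rank of the cell total, within each library and class, for genes with a count in at least 20% of the cells of every library and libraries with at least 15 cells. The Fisher z values of the 3 libraries were tested against 0 with limma and adjusted by the Benjamini-Hochberg method. The share of cells with a Klf2 count was taken after thinning each cell to 49408 counts, the 10th percentile of kept cells. Shares of classes carry exact (Clopper-Pearson) 95% intervals, and classes were set against libraries by a permutation test with 100000 resamples.

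The procedures were tested on simulated data. With counts drawn from the means and library sizes of the sums, the TE-like against ICM-like test recovered 33 of 100 genes changed 2-fold and 77 of 100 changed 4-fold, and called 13 unchanged genes, on 12258 genes. The correlation procedure recovered all 100 planted genes at a median rho of 0.724 in TE-like cells (9222 genes, 2 unchanged genes called) and of 0.735 in ICM-like cells (8681 genes, 3 called); weaker relations were not simulated. The tests between the TE-like clusters (10930 genes) recovered 13 of 100 at 2-fold and 56 of 100 at 4-fold, and those between the ICM-like sub-clusters (10709 genes) 6 and 52. They called 8 and 4 unchanged genes. In all of these comparisons of sums, TE-like against ICM-like included, unchanged genes took a larger share of the calls than the threshold on the adjusted p aims for. An adjusted p just under that threshold may therefore be too low. In the correlation procedure the share of unchanged genes among the calls was below the threshold.

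Alternatives were other size factors (RLE), DESeq2, no filter, a filter of at least 10 CPM in every sum of 1 class, no library block, each library left out in turn, limma on the mean log2 value over cells, minimums of 1000 and 4000 genes per cell, clusters from the 2000 most variable genes without the list genes, Leiden resolutions of 0.3 and 1.0, and thinned cells. Testing each TE-like cluster alone, and the tests between clusters of 1 class, were added after the data had been seen. So was a division of the barcodes of each library into 3 sets of 32 by their number, against which the clusters were tested with 10000 permutations. Copies of a ribosomal protein gene were counted by sequence, as other genes whose transcripts share at least 100 stretches of 31 bases with its coding transcripts. Gene positions came from GENCODE M21, which uses the same assembly as mm10, and 22127 of the 23154 symbols (95.6%) matched it. Of the 59 named genes, 9 overlap exons of another annotated gene, and because the strand setting is not given the counts of Cryab, Pvt1, Myl12b, Fgfr2, Wnt7b, Tpi1, Pdia6, Hsp90b1 and Dnmt3l are uncertain. Trim43b and Csta1 have close paralogs and are uncertain for that reason. Tools were R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9. Sequencing reads were not used here.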

Results

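Transcripts were counted in single cells of mouse blastocysts from a line in which the Klf2 locus carries a fluorescent reporter of fluid flow forces. The blastocyst holds the trophectoderm (TE), which forms the outer epithelium and pumps fluid into the cavity, and the inner cell mass (ICM), which gives rise to the epiblast (EPI) and the primitive endoderm (PrE). All 3 libraries belong to 1 group, and the question open to the counts is which genes, Klf2 among them, differ between these cell classes. Of 23154 genes, 17473 had at least 1 count. Library totals were 30573711, 27610866 and 54444536 counts for replicates 1, 2 and 3, and the 225 of 288 barcodes retained as cells held 99.8%, 99.7% and 99.7% of them. Median totals per cell were 286484, 345414 and 608734, with ranges of 7098 to 1553733, 9984 to 1540641 and 12897 to 2705412, and median numbers of genes were 7517, 6999 and 7158 in the same order. Ribosomal protein genes took 4.70% of the counts of the named cells in replicate 2, against 21.3% and 14.4% in replicates 1 and 3. Sox2, an epiblast regulator, and Xist, the RNA of X inactivation, were listed at 0 in all cells; the reason is not known, and neither gene was used as evidence.

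Marker genes divided the cells into 4 clusters. ICM-like cells formed 1 cluster of 101 cells led by Spic, Tdgf1, Epha4, Id3, Nrg2 and Tdh. TE-like cells formed 2 clusters, of 66 and 35 cells. Cluster 3 was led by Id2, Gata3, Ndrg1, Tmprss2 and Tspan8, while the 10 leading genes of cluster 2 held 5 TE markers, among them Dppa1, Id2 and Krt18, and 2 PrE markers, Lrp2 and Dab2. Ranked by the fold of mean CPM instead, the 10 leading genes of cluster 2 held no TE marker and 1 PrE marker, Lrp2, so Klf2, the number of called genes and the lists that passed are also given for each cluster alone. Summed CPM of the 18 TE markers was 7654 ± 2024 (SD, n = 3 libraries) in TE-like and 736 ± 72.7 in ICM-like cells, and that of the 10 EPI markers was 254 ± 85.0 and 832 ± 220. The 6 ICM markers separated the classes less, at 2521 ± 817 in TE-like and 3663 ± 675 in ICM-like cells. Their libraries overlapped, with TE-like cells of replicate 3 at 3212 and ICM-like cells of replicate 2 at 2988. Summed CPM of the 20 PrE markers was 2156 ± 1178 (SD, n = 3 libraries) in TE-like and 1372 ± 619 in ICM-like cells. That difference rested on Lrp2, since without it the sums were 1172 ± 663 and 1231 ± 560. The remaining 23 cells, 18 of them in replicate 1, stayed unnamed.

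TE-like cells made up 45.6% ± 10.4 (SD, n = 3) and ICM-like cells 44.7% ± 2.63 of the cells. In replicates 1, 2 and 3 the TE-like shares were 33.7% (exact 95% interval 23.7 to 44.9), 53.1% (40.2 to 65.7) and 50.0% (38.5 to 61.5), and the ICM-like shares were 44.6% (33.7 to 55.9), 42.2% (29.9 to 55.2) and 47.4% (36.0 to 59.1). Unnamed cells took 21.7% (13.4 to 32.1), 4.69% (0.977 to 13.1) and 2.56% (0.312 to 8.96). The division of cells over the 3 classes differed between libraries (permutation test of the chi-square statistic, p = 0.00032), while that over TE-like and ICM-like cells alone gave p = 0.38 in the same test. Cells were permuted singly, as if independent, although cells may share an embryo or a culture. These p-values therefore do not measure the spread that separate libraries would show. The column names of replicate 1, which held most unnamed cells, carry a sequencing prefix that differs from that of replicates 2 and 3 and that no label explains. Within libraries the clusters were also unevenly spread over the barcode numbers, taken after the data had been seen as 3 sets of 32. All 18 unnamed cells of replicate 1 were among barcodes 33 to 64, and 34 of the 35 cells of TE-like cluster 3 were among barcodes 1 to 32 of their libraries. The spread of the 4 clusters over these sets gave p = 1.00e-04, 0.0013 and 1.00e-04 in replicates 1, 2 and 3, and that of TE-like and ICM-like cells gave p = 0.122, 0.339 and 0.0002 (permutation tests of the chi-square statistic, again on single cells). What the barcode numbers stand for is not given in the sources used here. Among other cell types, summed CPM in TE-like and ICM-like cells was 24.2 and 27.1 for cumulus or granulosa markers, 0.667 and 6.76 for blood and 91.3 and 72.5 for oocytes; fibroblast markers were lower than blood markers in both. The oviduct list reached 1189 and 518, of which Epcam, an epithelial adhesion gene, gave 1063 and 496.

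Klf2, which encodes a flow-responsive zinc finger transcription factor, was higher in ICM-like cells. Its level was 399 ± 95.8 CPM (SD, n = 3 libraries) in ICM-like and 135 ± 22.8 CPM in TE-like cells, a 2.92-fold difference (log2 fold change TE-like over ICM-like -1.55, SE 0.18, adjusted p = 0.0021, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The direction was the same in each library, with 140, 155 and 110 CPM in TE-like and 295, 484 and 418 CPM in ICM-like cells of replicates 1, 2 and 3. Klf2 was also lower in TE-like cells within each of the 9 sets of 32 barcodes, with a mean log2 ratio of -1.55 ± 0.93 (SD over the 9 sets, which are not independent replicates). The sets held from 2 to 18 TE-like cells and counted alike. In cluster 2 alone the log2 fold change against ICM-like cells was -1.58 (edgeR, Benjamini-Hochberg adjusted p = 0.0219), and in cluster 3 alone it was -1.61 (adjusted p = 0.00704). Without the library block the log2 fold change was -1.56 and the call was lost (edgeR, Benjamini-Hochberg adjusted p = 0.644). In GENCODE M21, Klf2 (ENSMUSG00000055148) lies on chromosome 8 from 72319033 to 72321656 of the mm10 assembly, as 1 transcript of 3 exons that overlap no exon of another gene. Whether the reporter allele changes the number of Klf2 counts was not analysed here.

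**Figure D1:**
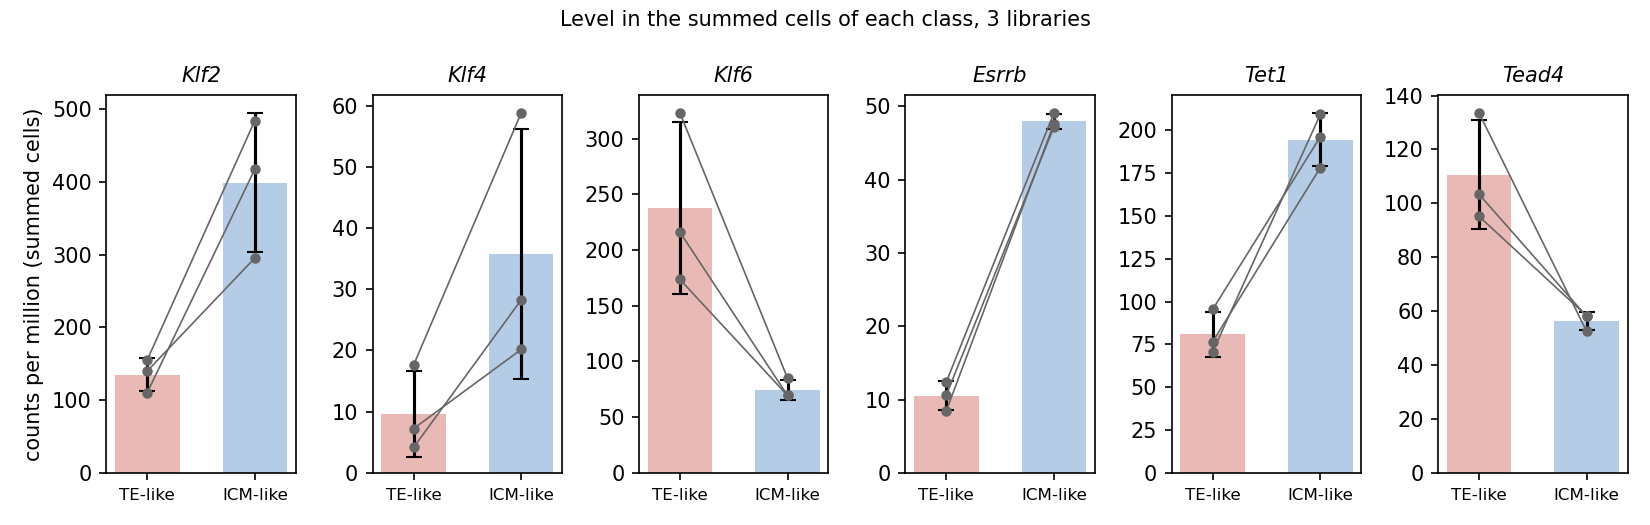
Level in CPM (vertical axis, from 0) of Klf2, Klf4, Klf6, Esrrb, Tet1 and Tead4, 1 panel each, in the summed TE-like and ICM-like cells (horizontal axis). Grey points joined by a line are 1 library, bars are the mean over 3 libraries and error bars the SD. Klf2 is higher in the ICM-like cells of each library, 295 to 484 CPM against 110 to 155 CPM.

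Other KLF genes went both ways. Klf4, a pluripotency factor, was 3.97-fold higher in ICM-like cells (log2 fold change -1.99, SE 0.39), and Klf6 was 3.09-fold higher in TE-like cells (log2 fold change 1.63, SE 0.18; edgeR, Benjamini-Hochberg adjusted p = 0.0235 and 0.00155). Klf5, a regulator needed for trophectoderm formation and named because the count is small, was 1.90-fold higher in TE-like cells (edgeR, Benjamini-Hochberg adjusted p = 0.0244). Of 14 measured KLF genes 2 were higher, 2 lower and 10 did not pass, and 5 passed when adjusted over the list alone. The list as a whole did not pass (limma's camera, adjusted p = 0.788, and adjusted p = 0.914 with an estimated correlation). The flow response and KLF2 pathway list had 1 of 23 members higher (Klf6), 2 lower (Klf2 and Klf4) and 20 not passing, with 4 called when adjusted over the list alone (camera, adjusted p = 0.488, and adjusted p = 0.884 with an estimated correlation). The call of Klf4 was lost without replicate 1 (edgeR, Benjamini-Hochberg adjusted p = 0.22) and without replicate 3 (0.181). None of the 11 mechanosensitive channel genes, which include Piezo1 and the polycystins, passed, over all genes tested or when adjusted over the list alone (0 in each case; camera, adjusted p = 0.926, and adjusted p = 0.947 with an estimated correlation).

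Over all genes, 642 of 12504 differed between TE-like and ICM-like cells, 429 higher and 213 lower in TE-like cells, each with the same sign in all 3 libraries (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05; 2313 genes had an unadjusted p below 0.05). Within the sets of barcodes, taken after the data had been seen, 625, 589 and 617 of these 642 genes kept their sign. In every set 551 of them did, so the sign of the others was not the same in all sets. Among called genes with a mean log2 CPM of at least 5 that were no clustering markers, the largest excess in TE-like cells was that of Adh1, an alcohol dehydrogenase, Tmprss2, a membrane-bound serine protease, and Slc15a2, a peptide transporter, with log2 fold changes of 6.59 (SE 0.47), 5.86 (SE 0.42) and 5.68 (SE 0.45) and adjusted p from 0.000197 to 0.000271 by the same test. Ndrg1 (4.69), the GABA transporter Slc6a13 (4.67), the acyl-CoA synthetase Acsl6 (4.48), the small heat shock protein gene Cryab (4.39), the cystatin gene Csta1 (4.22), the calpain gene Capn2 (4.13) and the kinase gene Wnk2 (3.93) followed on the log2 scale. Higher in ICM-like cells were the ETS repressor Etv6 (log2 fold change -3.27, SE 0.61), the threonine dehydrogenase gene Tdh (-2.96, SE 0.53), the ephrin receptor Epha4 (-2.81, SE 0.24) and the neuregulin Nrg2 (-2.70, SE 0.60), with adjusted p from 0.000403 to 0.0375 in edgeR's test with Benjamini-Hochberg adjustment. Id3 (-2.61), an inhibitor of helix-loop-helix factors, Fbxl20 (-2.60), Trim43b (-2.46), Rnf130 (-2.35), Mboat1 (-2.34) and the long noncoding RNA Pvt1 (-2.34) completed this group. Without replicate 1 or without replicate 3 the calls of Acsl6, Cryab, Etv6, Tdh, Nrg2, Id3, Trim43b, Rnf130 and Mboat1 were lost, at edgeR Benjamini-Hochberg adjusted p of up to 0.209.

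The number of genes called depended on the libraries and the tool. It was 144 without replicate 1, 824 without replicate 2 and 198 without replicate 3. DESeq2 called 1590 (863 higher and 727 lower), and edgeR without the library block called 0 with 691 genes at an unadjusted p below 0.05. All 59 named genes kept their direction in each of 18 alternatives that gave a value, and 24 of them, among them Adh1, Tmprss2, Epha4, Fbxl20 and Klf2, were called whichever library was left out. Apart from Klf2, named in advance, these genes were picked for passing in the same data, so their kept direction is weak support. Calls were lost for 30 named genes without replicate 1, for 4 without replicate 2 (Grb2, Tcf7l2, Rrm2 and Dtl) and for 25 without replicate 3, with edgeR Benjamini-Hochberg adjusted p of up to 0.276 (Perp). Of the 429 higher and 213 lower genes, 242 and 76 were also called for cluster 2 alone and 290 and 125 for cluster 3 alone. Of the 6 lists that passed in limma's camera for the whole class, all passed for cluster 2 alone and all but glycolysis (camera, adjusted p = 0.216) for cluster 3 alone. Lysosome and endocytosis and G2 and M phase genes passed for cluster 2 alone (camera, adjusted p = 0.00182 each). These settings were run at camera's preset correlation only, and for the whole class all 6 calls were lost at adjusted p from 0.378 to 0.832 with an estimated correlation.

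Genes of fluid transport and tight junctions build the epithelial seal and move ions and water. Of 20 measured members 8 were higher in TE-like cells, none lower and 12 did not pass, and 10 passed when adjusted over the list alone. In limma's camera this list had an adjusted p = 7.73e-08, and adjusted p = 0.378 with an estimated correlation, at which it no longer passed. Its estimated correlation was -0.0461, so correlation between its genes did not bring about that loss. Fry called this list alone among the 22 lists (adjusted p = 0.0129). Cldn4 and Cldn6, claudins of the tight junction, were 4.87-fold and 5.87-fold higher (log2 fold changes 2.28 and 2.55, SE 0.18 and 0.22), and Slc9a3r1, a scaffold of apical ion transporters, was 9.14-fold higher (3.19, SE 0.30; edgeR, Benjamini-Hochberg adjusted p from 0.000283 to 0.000555). Of 27 actomyosin and adhesion genes 9 were higher, 0 lower and 18 did not pass, and 13 passed when adjusted over the list alone. That list had an adjusted p = 6.45e-08 in camera, and its call was lost at an adjusted p = 0.378 with an estimated correlation and in fry (adjusted p = 0.0649). The nonmuscle myosin Myh10 was 5.58-fold higher (log2 fold change 2.48, SE 0.13), the cortical linker Msn 7.02-fold (2.81, SE 0.21) and the myosin light chain Myl12b 3.22-fold (1.69, SE 0.15; edgeR, Benjamini-Hochberg adjusted p from 7.18e-05 to 0.000403).

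Of 19 naive pluripotency regulators 7 were lower in TE-like cells, 1 higher and 11 did not pass, and 9 passed when adjusted over the list alone. In limma's camera the list had an adjusted p = 0.00327, and its call was lost at an adjusted p = 0.642 with an estimated correlation and in fry (adjusted p = 0.0965). The orphan nuclear receptor Esrrb was 4.61-fold higher in ICM-like cells (log2 fold change -2.21, SE 0.31), the DNA demethylase Tet1 2.42-fold (-1.27, SE 0.18) and Dppa2 1.89-fold (-0.92, SE 0.15; edgeR, Benjamini-Hochberg adjusted p from 0.00501 to 0.0106). The member that rose in TE-like cells was Klf5. In the p53 and apoptosis list 1 of 15 members was higher, 3 were lower and 11 did not pass, and 5 passed when adjusted over the list alone. In camera that list had an adjusted p = 0.000475, and its call was lost at an adjusted p = 0.832 with an estimated correlation, in fry (adjusted p = 0.275) and without replicate 3 (camera, adjusted p = 0.128). Trp53 (-1.54, SE 0.18) was lower in TE-like cells (edgeR, Benjamini-Hochberg adjusted p = 0.00207). Perp, a p53 target that also serves in desmosomes, was higher (1.10, SE 0.25; edgeR, Benjamini-Hochberg adjusted p = 0.0391). Also lower, and chosen after its value was seen, was the cell cycle inhibitor Cdkn1a (-0.73; edgeR, Benjamini-Hochberg adjusted p = 0.0447). The calls of Esrrb, Tet1, Dppa2 and Perp were lost without replicate 1 and that of Esrrb also without replicate 3, at edgeR Benjamini-Hochberg adjusted p of up to 0.276 (Perp).

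Of 16 glycolysis genes 5 were higher in TE-like cells, 0 lower and 11 did not pass, and 8 passed when adjusted over the list alone. The glucose transporter Slc2a3 was 4.86-fold higher (log2 fold change 2.28, SE 0.13), the hexokinase Hk2 3.40-fold (1.76, SE 0.24) and Tpi1 2.22-fold (1.15, SE 0.14; edgeR, Benjamini-Hochberg adjusted p from 8.64e-05 to 0.00367). Pgk1 (1.01) and Eno1 (0.82), chosen after their values were seen, were the other 2 (edgeR, Benjamini-Hochberg adjusted p = 0.0436 and 0.0200), and the call of Hk2 was lost without replicate 1 (adjusted p = 0.087). None of the 26 oxidative phosphorylation genes passed alone (0 called over all genes, 4 when adjusted over the list alone), while their median log2 fold change was 0.29. That list passed in limma's camera (adjusted p = 3.74e-06), and its call was lost at an adjusted p = 0.642 with an estimated correlation and in fry (adjusted p = 0.11). The glycolysis list passed narrowly (camera, adjusted p = 0.0421), and its call was lost at an adjusted p = 0.714 with an estimated correlation and in fry (adjusted p = 0.0704). In camera it did not pass with thinned cells (adjusted p = 0.102), without replicate 1 (0.0956) or without replicate 3 (0.0951). Without the library block, glycolysis (camera, adjusted p = 0.531) and oxidative phosphorylation (0.397) did not pass, while the other 4 lists that passed still did. Transcripts under 1000 bases were low in replicate 2, with a median log2 ratio of -2.07 against the other libraries over 377 genes.

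**Figure D2:**
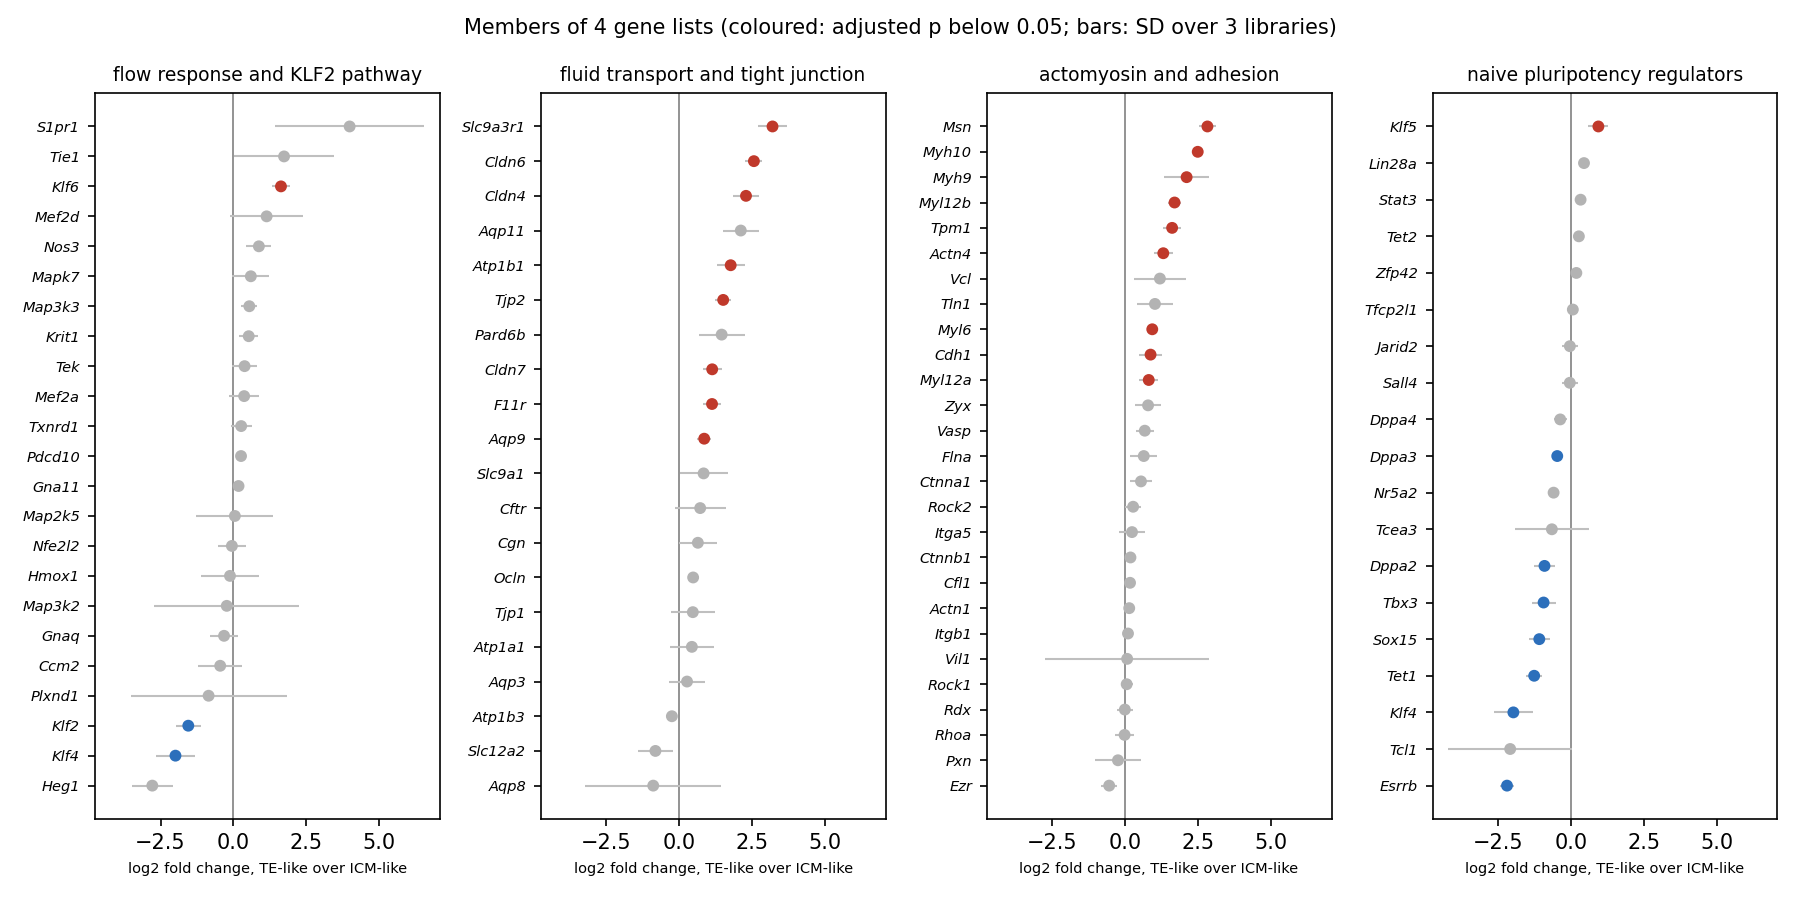
Log2 fold change of TE-like over ICM-like cells (horizontal axis) for the measured members (vertical axis) of 4 lists: flow response and KLF2 pathway, fluid transport, actomyosin, and naive pluripotency. Each point is 1 gene, red or blue where the adjusted p was below 0.05 and grey otherwise, and bars are the SD over 3 libraries. Members of the fluid transport and actomyosin lists that passed lie above 0, and 7 of the 8 that passed in the naive pluripotency list lie below 0.

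The other lists did not pass as wholes in the full data, although single members did. In limma's camera YAP and TEAD targets (adjusted p = 0.0489) and ER stress genes (0.0373) passed without replicate 2. Lysosome and endocytosis genes passed without replicate 3 (camera, adjusted p = 0.0207) and with clusters from the most variable genes (0.0161). YAP and TEAD targets had 3 of 14 genes higher, Myof (log2 fold change 5.85, SE 1.22), Amotl2 (3.22, SE 0.69) and the junction protein gene Ajuba (2.96, SE 0.65), none lower and 11 not passing. When adjusted over the list alone 3 passed (camera, adjusted p = 0.206, and adjusted p = 0.914 with an estimated correlation). Of 16 Hippo components only Tead4, the TEAD factor required for trophectoderm, passed over all genes (0.96, SE 0.22), and 3 when adjusted over the list alone (camera, adjusted p = 0.788, and adjusted p = 0.914 with an estimated correlation). In the FGF and ERK list the receptor Fgfr2 (2.13, SE 0.29) and the ERK phosphatase Dusp6 (3.54, SE 0.58) were higher and the adaptor Grb2 (-0.84, SE 0.20) lower in TE-like cells, 14 of 17 did not pass and 5 passed when adjusted over the list alone. The median (-0.24) and mean (0.39) log2 fold changes of this list differed in sign (camera, adjusted p = 0.788, and adjusted p = 0.914 with an estimated correlation). Lysosome and endocytosis genes had 5 of 21 higher, with Psap (0.93, SE 0.13), the tetraspanin Cd63 (0.74, SE 0.12) and the adaptor Ap2m1 (0.77, SE 0.13) among them, 2 lower and 14 not passing. Chosen after their values were seen, the others were Hexa (0.81) and Rab11a (1.04), which were higher, and Ctsb (-0.85) and Lamp2 (-0.75), which were lower. When adjusted over the list alone 10 lysosome and endocytosis genes passed (camera, adjusted p = 0.0535, and adjusted p = 0.642 with an estimated correlation). The ER stress list had 3 of 16 higher, the chaperones Hsp90b1 (0.65, SE 0.13) and Hspa5 (0.54) and the isomerase Pdia6 (1.05, SE 0.18), 1 lower, the asparagine synthetase gene Asns (-1.50, SE 0.23), and 12 not passing. When adjusted over the ER stress list alone 7 passed (camera, adjusted p = 0.223, and adjusted p = 0.914 with an estimated correlation). Among DNA methylation and chromatin genes Dnmt3b (1.56, SE 0.23) and Dnmt3l (1.41, SE 0.28) were higher, the deacetylase Hdac1 (-1.04, SE 0.13) and Trim28 (-0.76) were lower and 13 of 17 did not pass. Over the chromatin list, 5 passed when adjusted over the list alone (camera, adjusted p = 0.488, and adjusted p = 0.884 with an estimated correlation). These genes had adjusted p from 0.00227 to 0.0489 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without 1 library the calls of all but Fgfr2 and Hdac1 among those tested under the alternatives were lost, with edgeR Benjamini-Hochberg adjusted p of up to 0.255 (Tead4).

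Of 14 Wnt genes Wnt7b was higher (log2 fold change 2.43, SE 0.44) and Tcf7l2 lower (-1.30, SE 0.30) in TE-like cells, with 3 when adjusted over the list alone (camera, adjusted p = 0.926, and adjusted p = 0.954 with an estimated correlation). Among 16 BMP, Nodal and TGF beta genes only Id3, a BMP target, passed over all genes, with 1 when adjusted over the list alone (camera, adjusted p = 0.859, and adjusted p = 0.914 with an estimated correlation). Cholesterol synthesis had 1 of 16 genes higher, Pmvk (1.12, SE 0.19), and 1 when adjusted over the list alone (camera, adjusted p = 0.664, and adjusted p = 0.914 with an estimated correlation). In S phase genes Rrm2 (0.50, SE 0.11) was higher and Dtl (-0.86, SE 0.20) lower out of 20, with 2 when adjusted over the list alone (camera, adjusted p = 0.788, and adjusted p = 0.914 with an estimated correlation). No member passed, over all genes or when adjusted over the list alone, among 10 Notch genes, 21 G2 and M phase genes and 16 immediate early genes of dissociation (0 each; camera, adjusted p = 0.788, 0.484 and 0.488, and adjusted p = 0.914 with an estimated correlation for all 3). The 6 single genes passed at adjusted p from 0.00158 to 0.0459 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Each lost its call without replicate 1, and without 1 library the edgeR adjusted p rose to up to 0.227 (Rrm2).

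EPI-like and PrE-like cells, the outcome of the second fate decision of the blastocyst, were not compared, because the minimum of 8 cells of each per library, set before the data were examined, was met in no more than 1 library under any setting. Clustered again on EPI and PrE markers, the ICM-like cells gave 1 sub-cluster of 57 cells led by Serpinh1, Tdgf1, Spp1, Sparc, Upp1, Col4a2 and Lamb1, which mix markers of both classes, and 1 of 44 cells led by Lrp2, Dab2, Ypel2 and the TE marker Gata3. Neither could be named. Lrp2, Dab2 and Gata3 were also among the leading genes of TE-like cluster 2. At resolution 1.0 there were 9, 6 and 6 EPI-like and 13, 9 and 14 PrE-like cells in replicates 1 to 3, so that 1 library alone held 8 or more of both. With at least 4000 genes per cell there were 7, 4 and 4 EPI-like and 13, 11 and 10 PrE-like cells. No test was run for Klf2 or any list between EPI-like and PrE-like cells.

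Klf2 was counted in most cells of both classes. After thinning to 49408 counts, 70.1% ± 13.4 (SD, n = 3 libraries) of TE-like and 83.6% ± 8.45 of ICM-like cells had at least 1 Klf2 count, with 10 and 7 shallower cells left out. The shares in replicates 1, 2 and 3 were 84.6%, 58.1% and 67.6% in TE-like and 75.0%, 84.0% and 91.9% in ICM-like cells, so the direction in replicate 1 was opposite to that in the other libraries and to its CPM, and no order is read from the shares. Without thinning the shares were 82.2% and 96.4%. Klf2 in the 18 unnamed cells of replicate 1 had a median of 6.23 CPM and a mean of 45.0 CPM, most of which came from 2 cells, and their thinned share was 43.8%.

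Within a class, no gene varied with Klf2 from cell to cell beyond the test's threshold. In 101 ICM-like cells the highest mean correlations over 3 libraries were those of Ncl, encoding nucleolin (rho 0.50), Anapc5 (0.47), Map1lc3b (0.45), Pola2 (0.45) and Hdac1 (0.44), and the lowest were those of the focal adhesion kinase gene Ptk2 (-0.47), the integrin Itgav (-0.46), Tex14 (-0.45), Lcorl (-0.45) and Crtc3 (-0.44). Their adjusted p ranged from 0.0934 to 0.146 (limma with Benjamini-Hochberg adjustment), 0 of 8681 genes were called and 746 had an unadjusted p below 0.05. Over the 3 libraries the SD of rho ran from 0.02 (Anapc5) to 0.31 (Pola2, at 0.56, 0.06 and 0.64). In 101 TE-like cells the highest were Zfp706 (0.46), Calcoco2 (0.43), Gtf2h4 (0.43), Srp68 (0.41) and Kctd20 (0.41), and the lowest were Arid1a (-0.42), Axin1 (-0.42), Atrnl1 (-0.40), Tns3 (-0.40) and Lrba (-0.39), all at an adjusted p of 0.484 in the same limma test. Of 9222 genes 0 were called in TE-like cells and 676 had an unadjusted p below 0.05. Without the adjustment for the cell total, 3 genes were called in ICM-like cells (Anapc5, Ncl and Pola2; limma with Benjamini-Hochberg adjustment, adjusted p = 0.0473), and Pearson correlation called Ncl (adjusted p = 0.043). Over 99 shuffles of Klf2 among the cells, the number called had a median of 0 and a maximum of 3 in either class. The difference of the correlations between the classes was called for 0 of 8333 genes by limma, and 438 had an unadjusted p below 0.05. The correlations of the 2 classes were related with a rho of 0.252 across genes, which are not independent replicates.

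As groups, oxidative phosphorylation genes and ICM markers had correlations with Klf2 above those of other genes in ICM-like cells, with medians of 0.13 and 0.25, and TE markers lay below, with a median of -0.20. In limma's camera these had adjusted p = 1.62e-07, 1.97e-05 and 0.00594, and adjusted p = 0.555 with an estimated correlation. EPI markers, S phase and glycolysis were also above (adjusted p from 0.00918 to 0.0399) and FGF and ERK genes below (adjusted p = 0.0435) in camera. In TE-like cells actomyosin (adjusted p = 0.0159), Wnt (0.0174) and ER stress genes (0.0465) lay below and S phase, immediate early (0.0174 each) and EPI marker genes (0.0417) above in camera. None of these held in either class, with a lowest adjusted p = 0.54 with an estimated correlation. That setting has few degrees of freedom with so few libraries, so the losses cannot show that these groups are unrelated to Klf2. The correlations were adjusted for the cell total, but not for the set of barcodes or the cluster within a class. In ICM-like cells of replicate 1, Klf2 was 27.2 CPM in 1 set of barcodes, against 341 and 444 CPM in the others. It ran from 426 to 669 CPM in replicate 2 and from 156 to 466 CPM in replicate 3. Differences between sets of barcodes or clusters can therefore not be told apart from a relation of these groups to Klf2 within a class.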

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

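Of the tests in this part, those of depth, of other cell types and oocytes, of sets of barcodes, of pseudogene copies by sequence and of Klf2 under other weightings of cells were chosen only after the result was seen.

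Klf2 was counted in cells outside the comparisons. The 18 unnamed cells of replicate 1 had a median of 6.23 CPM and a mean of 45.0 CPM, most of which came from 2 cells. The barcodes under the gene minimum held 9 Klf2 counts in replicate 1, of which 7 were in 1 barcode, and 23 in replicate 2. Both lie above the floor of 3 counts set here. In replicate 3 these barcodes held 3 Klf2 counts, not above the floor, which does not show that Klf2 was absent.

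The unnamed cells are the first pattern: in replicate 1 all of them (100%) were among barcodes 33 to 64, and they had 2940 of 14349 genes raised and 3834 lowered over 4-fold against the 65 named cells, with Ano3, Ptafr, Epha7, Chst10 and Ggt7 among the most raised, ribosomal protein genes at 1.91% and Actb at 158 CPM. Their median total was 1.21 times that of the named cells, which argues against low depth, and no more than 9.09% of the genes of any list of cumulus, oviduct, blood or fibroblast markers were raised, with Star at 10.2 against 4.52 CPM and Epcam at 38.8 against 1074 CPM, which argues against RNA of those cells. Oocyte RNA stays open, since 22.2% of the oocyte list was raised, between the bounds, with Zp3 (448 against 32.1 CPM) and Gdf9 (17.3 against 5.53 CPM) above the named cells. Below them were Ooep (2.44 against 61.4 CPM) and, at few counts in either, Zp2 (0.188 against 0.955), Nlrp5 (0.470 against 1.56) and Bmp15 (0 against 0.151). Runs of 12 or more T were held by 24.0% of raised genes against 24.9% of length-matched genes (0.963 times), so the excess predicted for priming of genomic DNA was not seen. The search covered annotated transcripts only and no other genomic sequence, so it cannot decide on such priming, which stays open. Genomic DNA or unspliced RNA stays open too, since the ratio rose with exonic length at a rho of 0.208 across genes, between the bounds set for either outcome. A set of barcodes picked, handled or sequenced apart stays open too, as do embryo and culture, which the labels give for no cell, so no biological explanation was tested.

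The share of ribosomal protein genes in replicate 2 is the second pattern. Other genes with transcripts under 1000 bases lay lower than longer ones on the log2 scale (377 short genes at a median of -2.07 and 9035 longer ones at 0.45, a difference of -2.52), close to the -2.05 of the ribosomal protein genes, in line with a loss of short transcripts in that library. Reads set aside for pseudogene copies are argued against as the whole cause, since the 24 ribosomal protein genes with at most 2 copies by sequence had a median of -1.81 (SD 0.60). A part of the drop from this source stays open, since genes with few annotated pseudogenes (49, at a median of -1.93) lay 0.384 above those with many (9), between the bounds set in advance. No biological explanation was tested.

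The Klf2 difference between the classes is the third pattern. It did not rest on a few cells of high Klf2, since the mean of log2 values over cells gave -2.09, called with Klf2 higher in ICM-like cells. Deeper counting of ICM-like cells was not present, since their median totals were below those of TE-like cells in each library (262815 against 310803, 334025 against 414865 and 576864 against 638715), so the -1.90 from thinned cells excludes nothing further. An uneven spread of the classes over the sets of barcodes is argued against, since the mean log2 ratio within sets was -1.55, with Klf2 lower in TE-like cells in 9 of 9. An effect of the reporter allele on the counts, and of static or shaking culture, was not tested and stays open.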

How the results depend on the processing

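Of the settings in this part, cluster 2 alone and cluster 3 alone were chosen after the data had been seen. Klf2 stayed higher in ICM-like cells in all 18 alternatives (log2 fold change -1.36 to -2.09) and was called in 17; with no replicate block it was -1.56 (edgeR, Benjamini-Hochberg adjusted p = 0.644). The 642 genes called between TE-like and ICM-like cells became 0 with no replicate block, 1590 with DESeq2, 1303 with limma on mean log2 values and 337 for cluster 2 alone, and ranged from 144 to 824 when 1 library was left out (144 without replicate 1, 824 without replicate 2, 198 without replicate 3). The cause of these changes was not tested. Other settings gave 530 to 853. The 6 lists called became 0 with an estimated correlation and 1 with fry, and 4 to 8 in the other settings. Genes correlated with Klf2 in ICM-like cells rose from 0 to 3 without adjustment for the cell total and to 1 with Pearson correlation, and stayed at 0 in TE-like cells in all settings.

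Shares moved with the settings. With at least 1000 genes per cell the ICM-like share was 41.8%, the unnamed share 21.0% and the TE-like share of cells with Klf2 52.3%, the last at a lower thinning depth (16476 counts against 49408); without thinning it was 85.9% against 82.2%. With at least 4000 genes the ICM-like and unnamed shares were 25.0% and 32.1%. Clusters from the most variable genes gave 24.8% TE-like, 49.4% ICM-like and 25.8% unnamed cells, and resolution 1.0 gave 24.0% ICM-like and 30.4% unnamed cells. Without thinning, 96.4% of ICM-like cells had Klf2. All alternatives for EPI-like against PrE-like cells, for genes, Klf2 and lists, gave no value, because no setting had 8 cells of both in 2 libraries. In simulated data 33 of 100 genes changed 2-fold were recovered, so smaller differences were often not detectable at this depth and number of libraries. Changes were not planted in genes of low mean level, for which recovery may be lower.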

Other observations

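In this part the comparisons between clusters of 1 class, and the tests on splits of the sums, were all chosen after the clusters had been seen.

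Between the 2 TE-like clusters 4 lists passed while no single gene was called. Of the 35 cells of cluster 3, 34 were among barcodes 1 to 32, against 14 of the 66 of cluster 2, so a difference between clusters cannot be told apart from one between sets of barcodes. The median log2 fold change of cluster 3 over cluster 2 was -0.41 over 21 G2 and M phase genes, -0.31 over 21 lysosome and endocytosis genes, -0.31 over 16 cholesterol synthesis genes and 0.86 over 17 immediate early genes. In limma's camera these 4 lists had adjusted p = 0.000143, 0.00167, 0.0136 and 0.00436, and their calls were lost at an adjusted p = 0.731 with an estimated correlation. When adjusted over the list alone 5, 5, 0 and 5 members passed. Cholesterol synthesis did not pass without replicate 2 (camera, adjusted p = 0.748) or without the library block (0.065), and fry called none of the 4 (adjusted p from 0.163 to 0.288). Fry called the KLF family, with 0 of 14 members called (adjusted p = 0.021), which did not pass in camera (adjusted p = 0.627). No single gene was called among 11243 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (0 called, 1078 at an unadjusted p below 0.05), against 289 by DESeq2, 911 by limma on mean log2 values 29 by edgeR without replicate 1, 12 without a filter and 5 with thinned cells. Klf2 was at 128 ± 26.8 CPM in cluster 3 and 136 ± 61.6 CPM in cluster 2 (SD, n = 3 libraries; SE of the log2 fold change 0.40).

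The ICM-like sub-clusters differed in 3 of 11073 genes, all lower in the sub-cluster of 57 cells (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; 855 at an unadjusted p below 0.05). These were 2310040G24Rik (log2 fold change -3.52), Ypel2 (-2.07) and Naalad2 (-1.84), the first named because the count is small. The direction was not shared by all other settings: DESeq2 called 250 (117 higher and 133 lower), limma on mean log2 values 129 (99 and 30), edgeR without a filter 123 (66 and 57), with thinned cells 47 (17 and 30) and with the stricter filter 24 (7 and 17). Without replicates 1, 2 and 3 in turn edgeR called 5 (0 and 5), 1 (1 and 0) and 38 (11 and 27), and without the library block 0, with 218 at an unadjusted p below 0.05. The glycolysis and ER stress lists passed upward in that sub-cluster in camera (adjusted p = 0.0287 each) with 0 of 16 members called in either, and 5 and 1 when adjusted over the list alone. Both calls were lost at an adjusted p = 0.903 with an estimated correlation, in fry (adjusted p = 0.533), without the library block (camera, adjusted p = 0.155) and without replicate 1 (0.146). Klf2 was 482 against 74.9, 493 against 497 and 318 against 555 CPM in replicates 1, 2 and 3, without a common direction. In replicate 1, 8 of the 15 cells of the other sub-cluster, but 1 of the 22 of this one, were among barcodes 33 to 64, where Klf2 of ICM-like cells was 27.2 CPM, against 341 and 444 CPM in the other sets.

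The 6 sums of each comparison can be split in 10 ways, too few for a share under 0.05. Most of these splits put both sums of a library on the same side, which ignores the pairing by library. The real split of TE-like and ICM-like sums called 642 genes and the highest of the others 0, and 1 of the 10 splits gave as many as the real one. Each of the others has sums of both classes on either side, so the class difference adds to its spread. Their 0 is therefore not a level of calls without a difference. For the TE-like clusters the real split and the highest other both called 0, so all 10 splits gave as many, and for the ICM-like sub-clusters the real split called 3 and the highest other 0, with 1 of 10 giving as many.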
